A study of Mus musculus with 20 samples.

How the data were processed

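Hearts of wild-type (WT) and OGFOD1-knockout (KO) mice that had received vehicle or isoproterenol were weighed, frozen and powdered, and RNA from a small aliquot was made into stranded total RNA libraries, per the labels' protocols. Total RNA libraries keep non-polyadenylated and mitochondrial transcripts. The deposited table held raw counts per gene for 20 libraries and 55335 versioned Ensembl gene IDs. The authors' counts were made with HISAT2 2.1.0 and featureCounts 1.6.3 on the GRCm38 genome build, per the submitters' processing notes, which also name R 3.6.0 and limma 3.40.6. The annotation release, the strand setting and the treatment of reads that map to several genes were not given in the sources used here. Reads of near-identical paralogs such as Myh6 and Myh7, and of overlapping or antisense genes, may therefore have been split or dropped, and values of such genes are uncertain. No other table was used, and 0 columns of the table lacked a sample.

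Groups were taken from the labels, 5 libraries in each of 4 groups. Replicate numbers follow the order of the records and pair no libraries across groups. Symbols, gene types and coordinates came from GENCODE vM21 on GRCm38, in which 55154 of the IDs were found, 54587 of them with the same version.

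Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with the filterByExpr function, which left 14878, and libraries were scaled by the trimmed mean of M values (TMM). All 20 libraries entered 1 quasi-likelihood fit with a mean per group and robust estimation, which had 16 residual degrees of freedom and a common biological coefficient of variation of 0.119. The 5 comparisons were isoproterenol against vehicle in WT, the same in KO, KO against WT under vehicle, KO against WT under isoproterenol, and the difference between the isoproterenol responses. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE). The SE of a median over a set of genes is taken over its genes as if independent, and does not measure the spread between libraries. CPM values are counts scaled to library size after TMM scaling.

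Gene lists for pathways, complexes and cell types, 39 in all, were fixed before the data were examined, together with the groups, tests and alternatives. The 37 lists with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated for each list, and with the rotation test fry. The lymphocyte and skeletal muscle lists had fewer tested genes and were left out. Members were also counted with p-values adjusted over the list alone. Named genes were, per comparison, the 10 largest rises and the 10 largest falls among genes that passed, had an average log2 CPM of at least 0 and carried a named symbol. Ogfod1, Rps23 and 8 markers of hypertrophy and fibrosis were reported whatever their p, as were up to 4 members with the smallest p per list. Some genes that these rules name are not reported here. Among these members, examples were mostly chosen, after their values were seen, from those that kept their call in every alternative.

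Sizes of the isoproterenol responses were compared over genes that passed for the average effect, by an exact permutation test. Overlaps of calls were tested with Fisher's exact test. The comparison of isoproterenol in WT and the difference between responses were tested on simulated counts. Each had 200 changed genes, of which 100 changed 1.5-fold and 100 changed 2-fold. The other comparisons were not simulated. For isoproterenol in WT, 67% of the former and 79% of the latter were recovered over 14863 genes, with 6 false among 152 calls. For the difference between responses the false calls were 4 of 94 over 14867 genes. Alternatives were DESeq2 1.42.0, limma-voom without and with quality weights, other scalings and filters, removal of mitochondrially encoded genes, 2 surrogate variables from sva 3.50.0, a fit of only the groups compared, and leaving out each library in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.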

Results

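RNA from the hearts of C57BL/6N mice aged 3 to 5 months was sequenced to ask how loss of OGFOD1 alters the cardiac response to isoproterenol. OGFOD1 is a 2-oxoglutarate- and iron-dependent oxygenase that hydroxylates a prolyl residue of the ribosomal protein Rps23. Isoproterenol is a beta-adrenergic agonist whose chronic infusion is a standard model of cardiac hypertrophy. Wild-type (WT) and OGFOD1-knockout (KO) mice had received vehicle, phosphate-buffered saline with sodium ascorbate, or the same solution with isoproterenol from an osmotic minipump for 2 weeks. The 20 libraries fell into 4 groups of 5. The labels do not say that each library of a group came from a different mouse, so that p-values measure the spread between libraries. Total counts ranged from 14609808 to 43671055 per library. The mitochondrial ribosomal RNA mt-Rnr2 took 36.9% to 46.4% of them, and counts outside the mitochondrial genome came to 5.92 to 17.1 M. Of 55335 annotated genes, 14878 passed the filter on low counts and were tested. No libraries of a group were alike within sampling noise, so that none was a plain copy of another, and each was counted as 1 sample. Libraries made from the same heart could also differ by more than that noise, so that this check does not settle the number of mice.

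The targeted gene separated the genotypes in every library. Ogfod1 (ENSMUSG00000033009; GRCm38 chromosome 8, 94037198 to 94067921) measured 16.9 to 20.9 counts scaled to library size (CPM) in the 5 WT vehicle libraries and 18.7 to 21.8 CPM in the 5 WT isoproterenol libraries. The KO vehicle libraries lay between 2.49 and 4.08 CPM, and the KO isoproterenol libraries between 2.39 and 4.13 CPM. The group means were 19.2 ± 1.44, 20.2 ± 1.35, 3.19 ± 0.582 and 3.18 ± 0.681 CPM (SD, n = 5 each). The log2 fold change between genotypes was −2.58 (SE 0.113, edgeR adjusted p = 5.24e-16) under vehicle and −2.64 (SE 0.115, adjusted p = 5.32e-16) under isoproterenol. Which part of the gene had been deleted was not given in the sources used here, and the counts that remained in the KO were not assigned to exons. Isoproterenol left Ogfod1 without a detectable change in WT (log2 fold change 0.07, SE 0.0968, adjusted p = 0.718) and in KO (0.01, SE 0.131, adjusted p = 0.983). None of the 50 tested genes within 2 Mb of Ogfod1 passed the edgeR test in either knockout comparison, and 2 of them had an unadjusted p under 0.05 under vehicle. Rps23, the substrate of OGFOD1, had a log2 fold change of 0.11 between genotypes under vehicle (SE 0.0887, adjusted p = 0.815) and 0.01 under isoproterenol (SE 0.0893, adjusted p = 0.975).

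**Figure D1:**
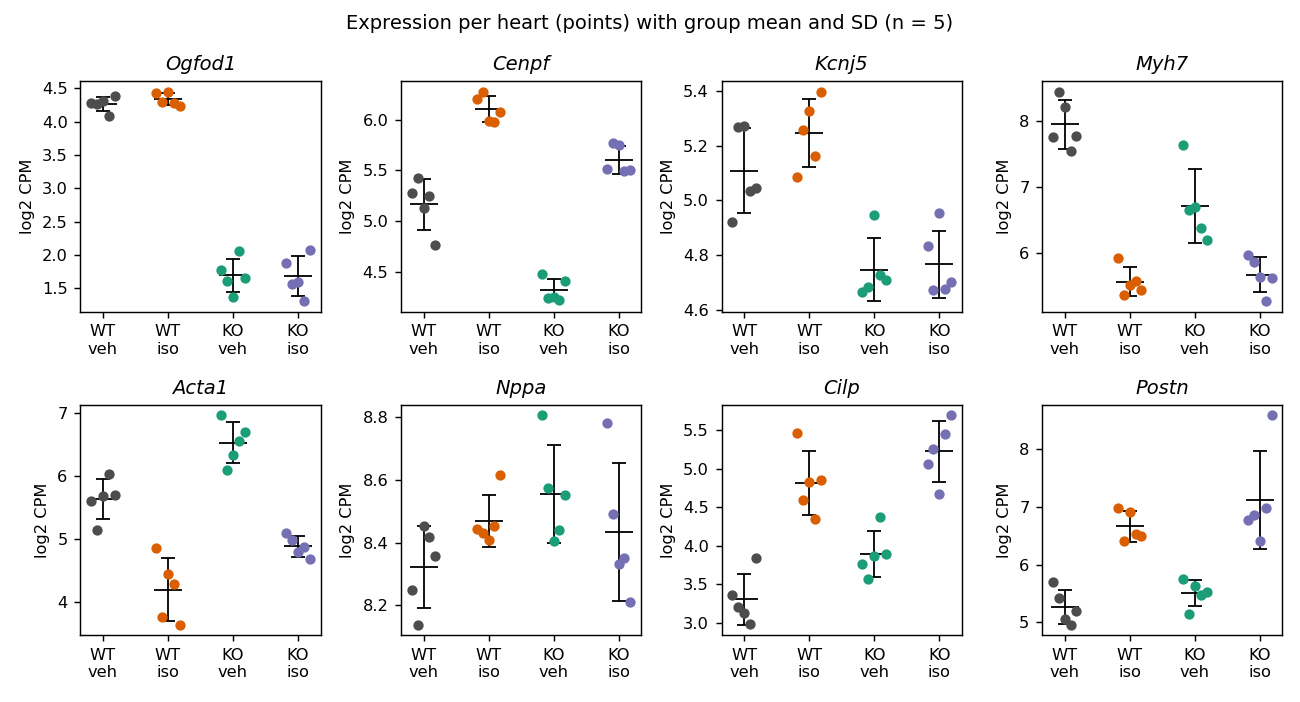
Normalised expression (log2 CPM, y axis) of 8 genes in the 5 libraries (points) of each of the 4 groups (x axis), with the group mean (horizontal bar) and SD (error bar). Ogfod1 lay at or below 4.13 CPM in every KO library and at or above 16.9 CPM in every WT library, and Myh7 was lower with isoproterenol than with vehicle in both genotypes.

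Isoproterenol lowered Myh7, Acta1 and Myh6 and raised Postn and Cilp in WT hearts. Myh7, the slow (beta) myosin heavy chain of the fetal and stressed heart, fell from 254 ± 67.0 to 47.8 ± 7.66 CPM (SD, n = 5), a log2 fold change of −2.41 (SE 0.257, adjusted p = 1.75e-05). Acta1, the skeletal alpha actin that is also expressed in the fetal heart, fell by 1.40 on the log2 scale (SE 0.220, adjusted p = 6.58e-04). Myh6, the fast myosin heavy chain of the adult mouse heart, had a log2 fold change of −0.50 (SE 0.0881, adjusted p = 3.62e-04). The natriuretic peptide genes Nppa and Nppb, commonly used as markers of hypertrophy, did not pass (log2 fold changes of 0.14 and 0.31, adjusted p = 0.345 and 0.437). The matrix protein genes Postn (log2 fold change 1.40, SE 0.337, adjusted p = 0.0161) and Cilp (1.52, SE 0.243, adjusted p = 7.63e-04) rose, and all 5 isoproterenol libraries lay above the vehicle mean. Col3a1 and Col1a1, which encode fibrillar collagens, had log2 fold changes of 0.99 (SE 0.357, adjusted p = 0.101) and 0.29 (SE 0.653, adjusted p = 0.843) and did not pass. Without WT vehicle replicate 2 and KO isoproterenol replicate 5, left out after the data had been seen, Col3a1 passed (1.01, adjusted p = 0.00450), as it did in DESeq2 (adjusted p = 0.0478) and with 2 surrogate variables (0.85, adjusted p = 0.00464).

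In total 691 genes were higher and 613 lower with isoproterenol in WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 119 of them changed by more than 2-fold. The largest rise among named genes was that of Snhg11, a host gene of small nucleolar RNAs that the annotation lists as protein-coding, at a log2 fold change of 3.09 (SE 0.379, adjusted p = 1.64e-05). It was counted only 1 to 11 times per WT vehicle library. Counts were also low for Clec4n (5 to 17) and Rtl3 (10 to 22) under vehicle and for Edn3 (6 to 24) under isoproterenol. Further rises were those of Clec4n (1.73), a lectin receptor of myeloid cells, the retrotransposon-derived Rtl3 (1.70), the leukotriene receptor gene Cysltr1 (from 1.13 to 3.19 CPM), the matricellular Ccn5 (1.47), the thyroid hormone deiodinase gene Dio2 (1.42), Dct (1.40) and Ctnnal1 (1.39). Ctnnal1 rose from 17.4 ± 1.14 to 45.8 ± 4.77 CPM (SD, n = 5). The genes with the largest falls after Myh7 included Edn3 (−1.78), which encodes an endothelin, Colq (−1.76), the collagen tail of acetylcholinesterase, Scgb1c1 (−1.62), the Wnt antagonist gene Sfrp5 (−1.38), Lgi1 (−1.31) and the myosin light chain kinase gene Mylk4 (−1.20). Lars2, mitochondrial leucyl-tRNA synthetase, had a log2 fold change of −3.30 (SE 0.967, adjusted p = 0.0436) that came from 1 library. WT vehicle replicate 2 measured 9.18 log2 CPM against 3.56 to 4.26 in the rest of its group, together with high counts of the rRNA-like gene Gm42418 (13.2 against 6.36 to 7.63 log2 CPM in the other 19 libraries), and without it the log2 fold change of Lars2 was −0.28 (adjusted p = 0.540). Its call was also lost without each of the 5 WT isoproterenol libraries in turn.

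Genes of the extracellular matrix and fibrosis were higher with isoproterenol in WT, in a list test that did not hold with an estimated correlation. Of 34 tested members of the list, 11 rose and none fell, among them the collagen gene Col8a1 (log2 fold change 0.97), the collagen crosslinking enzyme gene Loxl2 (0.72) and the protease inhibitor gene Timp1 (0.99). When adjusted over the list alone, 17 passed. The median log2 fold change was 0.62 (camera adjusted p = 3.09e-12, adjusted p = 0.218 with an estimated correlation, fry adjusted p = 0.0106). Fibroblast markers rose in 4 of 8, with Pi16 (0.88), Lum (0.56) and Dpt (0.36) among them (6 of 8 adjusted over the list alone, median 0.20, adjusted p = 1.77e-05, adjusted p = 0.0354 with an estimated correlation). This was the only list of the 37 whose call in this comparison held with an estimated correlation. Of the macrophage markers, 6 of 14 rose and 12 passed adjusted over the list alone, including the mannose receptor gene Mrc1 (0.52) and Lgals3 (0.81), with a median of 0.50 (adjusted p = 2.24e-07, adjusted p = 0.192 with an estimated correlation). Endothelial markers gave 3 of 12 members higher, with Pecam1 at 0.29 (4 higher and 1 lower adjusted over the list alone, median 0.13, adjusted p = 0.0633). Smooth muscle and pericyte markers gave 2 higher and 1 lower of 11, with Rgs5 at 0.43 (4 higher and 1 lower adjusted over the list alone, median 0.12, adjusted p = 0.0927). Without WT vehicle replicate 2 and KO isoproterenol replicate 5, a choice made after seeing the data, 17 matrix genes were higher (adjusted p = 0.0499 with an estimated correlation).

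Fatty acid oxidation, sarcomere and calcium handling genes were lower with isoproterenol in WT, in list tests that did not hold with an estimated correlation. Fatty acid oxidation lost 15 of 31 genes, with none higher, among them the dehydrogenase gene Hadh (log2 fold change −0.57), Decr1 (−0.50), Ech1 (−0.54) and the carnitine palmitoyltransferase gene Cpt2 (−0.38). Adjusted over the list alone 19 were lower, and the median was −0.27 (adjusted p = 6.05e-15, adjusted p = 0.150 with an estimated correlation, fry adjusted p = 5.40e-04). Sarcomere genes fell in 9 of 20, with Myom2 (−0.92), Myl2 (−0.40) and Myoz2 (−0.45) as examples (12 adjusted over the list alone, median −0.22, adjusted p = 2.98e-08, adjusted p = 0.218 with an estimated correlation, fry adjusted p = 0.00484). Calcium handling genes fell in 5 of 19, including the calcium channel subunit gene Cacna2d1 (−0.49) and Hrc (−0.55), and 1 was higher and 7 lower adjusted over the list alone (adjusted p = 0.00669, adjusted p = 0.218 with an estimated correlation). Of 33 nuclear-encoded oxidative phosphorylation genes only Sdha (−0.29) was lower, over all genes and adjusted over the list alone (median −0.06, adjusted p = 0.0633). None of the 13 mitochondrially encoded protein genes passed singly (median −0.29, adjusted p = 0.00146, adjusted p = 0.380 with an estimated correlation). In glycolysis, Hk2 (−0.45) fell and Ldha (0.31) rose, with 2 higher and 2 lower of 23 (2 higher and 4 lower adjusted over the list alone, adjusted p = 0.728). Without both libraries that stood apart, 16 fatty acid oxidation and 11 sarcomere genes were lower, each list at adjusted p = 0.0499 with an estimated correlation. Nuclear-encoded oxidative phosphorylation then had 6 lower and a median of −0.11 (adjusted p = 2.72e-04, adjusted p = 0.562 with an estimated correlation).

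Receptor and stress genes gave smaller groups in WT. Of the fetal and hypertrophy list, 3 of 15 rose and 3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.569), with Fhl1 (log2 fold change 0.78) and Uchl1 (0.74) higher and Myh7 and Acta1 lower. Beta-adrenergic and cAMP signalling gave 4 higher and 3 lower of 26 (5 and 4 adjusted over the list alone, adjusted p = 0.872): the alpha-1A adrenergic receptor gene Adra1a fell (−0.54) and the receptor kinase gene Grk5 rose (0.68). Hypoxia targets rose in 6 of 13, with 1 lower (the same counts adjusted over the list alone), among them Ankrd37 (1.34), Hmox1 (0.89) and Egln3 (0.50) (median 0.23, adjusted p = 0.00576, adjusted p = 0.150 with an estimated correlation). The interferon-stimulated genes gave 2 higher of 15 (5 adjusted over the list alone, adjusted p = 0.00184, adjusted p = 0.380 with an estimated correlation). Ifit3 (0.68, adjusted p = 0.0142) was the first of these by p and lost its call without WT isoproterenol replicate 4. Genes of protein synthesis changed little in WT: 2 of 77 cytosolic ribosomal protein genes were lower and none passed adjusted over the list alone (median −0.02, adjusted p = 0.370, and without both libraries that stood apart adjusted p = 0.0110, adjusted p = 0.733 with an estimated correlation), and 4 of 41 translation factors were lower, including Eef1a2 (−0.40) and Eif4e (−0.25) (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.00184, adjusted p = 0.192 with an estimated correlation).

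In KO hearts isoproterenol raised Postn and Col3a1 and lowered Acta1 and Myh7. Postn rose from 45.9 ± 6.74 to 165 ± 125 CPM (SD, n = 5), a log2 fold change of 1.85 (SE 0.338, adjusted p = 0.00236), and Col3a1 by 1.73 (SE 0.363, adjusted p = 0.00632). Col1a1 had a log2 fold change of 2.00 (SE 0.650) and did not pass (adjusted p = 0.0664), whereas it passed in DESeq2 (adjusted p = 0.0147) and with 2 surrogate variables (0.82, adjusted p = 0.0474). Acta1 fell by 1.67 on the log2 scale (SE 0.216, adjusted p = 1.07e-04) and Myh7 by 1.12 (SE 0.249, adjusted p = 0.00930), from 112 ± 50.7 to 51.7 ± 9.31 CPM. In a fit of only the 2 groups compared, Col3a1 and Myh7 lost their calls (adjusted p = 0.0726 and 0.0556). Myh6 (−0.21, adjusted p = 0.138), Nppa (−0.12, adjusted p = 0.471) and Nppb (−0.29, adjusted p = 0.466) did not pass. With 2 surrogate variables Myh6 passed (adjusted p = 4.22e-04). KO isoproterenol replicate 5 stood apart in matrix and smooth muscle genes: Col1a1 measured 8.57 log2 CPM against 4.70 to 5.82 in the other 4 libraries, elastin (Eln) 10.9 against 5.04 to 5.46, and the smooth muscle gene Tagln 7.68 against 4.16 to 4.90. Adipocyte markers lay above the other 4 libraries by a median of 1.66 on the log2 scale (6 genes), and erythroid and platelet markers by 0.79 (9 genes). Without that library the log2 fold changes were 1.26 for Postn, 1.07 for Col3a1 and 0.61 for Col1a1 (adjusted p = 0.412 for Col1a1), and the first 2 passed.

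In KO, 706 genes were higher and 638 lower with isoproterenol, 116 of them by more than 2-fold. With upper quartile scaling the balance turned, to 641 higher and 767 lower. Snhg11 again had the largest rise (log2 fold change 3.37, SE 0.347, adjusted p = 1.28e-06), from only 4 to 21 counts per KO vehicle library. Further genes that rose were the secreted Wnt modulator gene Sfrp2 (2.01), Ltbp2 (1.68), which encodes a protein of the elastic fibre, the tenascin gene Tnc (1.67), the metalloprotease gene Adam8 (1.65), the protease inhibitor gene Serpina3n (1.54), Clec4n (1.51) and Olfml2b (from 13.9 to 38.9 CPM). Without KO isoproterenol replicate 5 the log2 fold changes were 1.16 for Sfrp2 and 0.88 for Tnc, both past the threshold (adjusted p = 0.0211 and 0.0380). Tnc lost its call without KO vehicle replicate 2, 4 or 5 (highest adjusted p = 0.0686), and both Sfrp2 and Tnc lost it in a fit of only the 2 groups compared. The largest falls included those of Scgb1c1 (−2.24), Colq (−1.78), the G protein subunit gene Gnb3 (−1.69), Edn3 (−1.55), Sfrp5 (−1.37), the nicotinamide riboside kinase gene Nmrk2 (−1.32), Lgi1 (−1.28) and the integrin gene Itgb6 (−1.27).

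The matrix list rose in 25 of 34 genes in KO and in 31 adjusted over the list alone, including Col8a1 (log2 fold change 0.73), the proteoglycan gene Bgn (0.64), Timp1 (1.24) and Col12a1 (0.89). Its median was 1.11 (camera adjusted p = 1.34e-26, adjusted p = 0.0694 with an estimated correlation). KO isoproterenol replicate 5 lay above the other 4 libraries of its group by a median of 1.05 on the log2 scale over these 34 genes. Without it and WT vehicle replicate 2, 21 genes were higher and the median was 0.60 (adjusted p = 0.0423 with an estimated correlation). Smooth muscle and pericyte markers gave 3 of 11 higher, with Notch3 (0.45) and Pdgfrb (0.29) (5 adjusted over the list alone, median 0.45, adjusted p = 0.00367, adjusted p = 0.345 with an estimated correlation). Without the same libraries 2 were higher, the median was 0.08 and the adjusted p 0.126, and Notch3 lost its call (adjusted p = 0.0537) on leaving out KO isoproterenol replicate 5 alone. The call of Pdgfrb was lost without KO vehicle replicate 2 (adjusted p = 0.0542). Fibroblast markers rose in 3 of 8, namely Pi16 (0.86), Lum (0.64) and Dpt (0.38) (5 adjusted over the list alone, median 0.17, adjusted p = 3.31e-06, adjusted p = 0.0231 with an estimated correlation). Macrophage markers rose in 4 of 14, including Lgals3 (0.86), Mrc1 (0.44) and Ccr2 (0.96) (6 adjusted over the list alone, median 0.26, adjusted p = 7.11e-05, adjusted p = 0.308 with an estimated correlation). Endothelial markers gave 1 lower of 12, the receptor gene Kdr (−0.31), over all genes and over the list alone (adjusted p = 0.639).

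Fatty acid oxidation genes fell in 16 of 31 in KO, with Hadh (log2 fold change −0.65), Hadhb (−0.55), Acadm (−0.45) and Cpt2 (−0.38) as examples (17 adjusted over the list alone, median −0.29, adjusted p = 1.20e-16, adjusted p = 0.0633 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 10 of 33, including Ndufs4 (−0.44) and Ndufa9 (−0.28), and 22 passed adjusted over the list alone (median −0.20, adjusted p = 6.26e-10, adjusted p = 0.365 with an estimated correlation). Sarcomere genes fell in 9 of 20, among them Myom2 (−0.82), Myl3 (−0.53) and Myl2 (−0.47) (10 adjusted over the list alone, median −0.19, adjusted p = 2.96e-09, adjusted p = 0.182 with an estimated correlation). Calcium handling gave 1 higher and 5 lower of 19, with Cacna2d1 (−0.32) and S100a1 (−0.38) lower (2 and 6 adjusted over the list alone, adjusted p = 6.35e-04, adjusted p = 0.182 with an estimated correlation). Atrial myocyte markers fell in 4 of 7, namely Mybphl (−0.52), Myl7 (−0.61), Myl4 (−0.37) and Sln (−0.53) (4 adjusted over the list alone, median −0.37, adjusted p = 1.49e-04, adjusted p = 0.182 with an estimated correlation). Glycolysis gave 1 higher and 5 lower of 23, with Pgam2 (−0.41) and Hk2 (−0.35) lower (2 and 5 adjusted over the list alone, adjusted p = 0.00781, adjusted p = 0.399 with an estimated correlation). KO isoproterenol replicate 5 lay below the other 4 libraries of its group in sarcomere and fatty acid oxidation genes, by medians of −0.38 and −0.27 on the log2 scale. Without both libraries that stood apart, 16 fatty acid oxidation, 9 sarcomere, 7 nuclear-encoded oxidative phosphorylation and 4 atrial genes were lower and 1 sarcomere gene was higher.

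Chaperones of the endoplasmic reticulum fell in 7 of 20 in KO, with Calr (log2 fold change −0.40), Hyou1 (−0.43), Canx (−0.38) and Hspa5 (−0.40), which encodes BiP, among them (9 adjusted over the list alone, median −0.22, adjusted p = 1.99e-06, adjusted p = 0.0633 with an estimated correlation). Without both libraries that stood apart 9 were lower, and the call held with an estimated correlation (adjusted p = 0.0339). Heat shock genes fell in 5 of 12, including the mitochondrial chaperonin genes Hspd1 (−0.47) and Hspe1 (−0.34) and the cytosolic Hspa8 (−0.29). Their median was −0.16 while their mean was 0.07, and the test gave a fall (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.00291, adjusted p = 0.0633 with an estimated correlation). Targets of NRF2, the regulator of antioxidant genes, rose in 6 of 11, including the glutathione synthesis genes Gclm (0.59) and Gclc (0.36) and Hmox1 (0.74) (8 adjusted over the list alone, median 0.25, adjusted p = 6.95e-05, adjusted p = 0.182 with an estimated correlation). No cytosolic ribosomal protein gene passed in edgeR among 77, either over all genes or adjusted over the list alone (median −0.09, adjusted p = 6.35e-04, adjusted p = 0.634 with an estimated correlation). Without both libraries 5 of 78 were lower and the median was −0.13 (adjusted p = 2.53e-07, adjusted p = 0.533 with an estimated correlation). Translation factors gave 1 higher and 5 lower of 41, with Eif4e (−0.32) and Eef1d (−0.25) lower (1 and 7 adjusted over the list alone, adjusted p = 0.00202, adjusted p = 0.182 with an estimated correlation). Of the aminoacyl-tRNA synthetases, Kars (−0.30) and Dars (−0.32) were lower of 20 (4 adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.411 with an estimated correlation). The fetal and hypertrophy list gave 4 higher and 4 lower of 15, with Fhl1 (0.93) and Uchl1 (0.62) higher (4 and 5 adjusted over the list alone, adjusted p = 0.776).

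**Figure D2:**
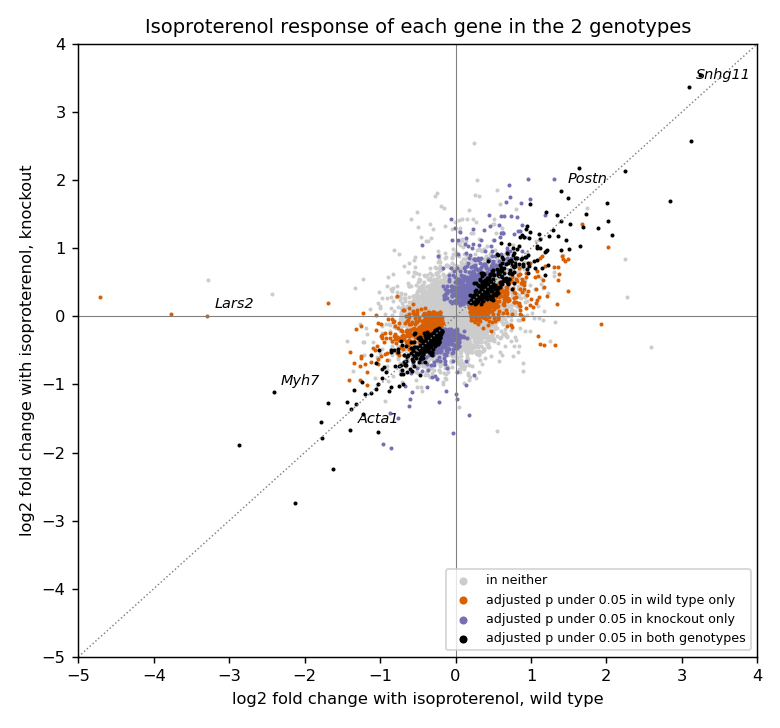
Log2 fold change with isoproterenol in WT (x axis) against that in KO (y axis) for each of the 14878 tested genes, coloured by the genotype in which the gene passed the test, with the line of equal change dotted. The 551 genes that passed in both genotypes had the same sign in both.

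The isoproterenol responses of the genotypes were next compared gene by gene. Of the genes called in WT, 301 of the higher and 250 of the lower were also called in the same direction in KO, against 32.8 and 26.3 for independent lists of these sizes (Fisher's exact test, p = 1.61e-231 and 3.50e-192). No gene was called in opposite directions among the 551 called in both, and 93.3% of the WT calls and 94.1% of the KO calls had the same sign in the other genotype. The libraries of these comparisons were distinct. Genes are not independent replicates, however, and both comparisons come from 1 fit, so that the Fisher p-values only describe the overlap. Across all 14878 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.507 (Spearman 0.467). No gene passed the edgeR test of the difference between the responses, with a smallest adjusted p of 0.231 and 1142 genes at an unadjusted p under 0.05. DESeq2, limma-voom and limma-voom with quality weights also called 0, with 1236, 1169 and 1457 genes at an unadjusted p under 0.05. With no filter on low counts 34 genes passed, and without WT vehicle replicate 2 and KO isoproterenol replicate 5 there were 4. The largest difference among the marker genes was that of Col1a1 (1.71, SE 0.913, adjusted p = 0.673), and without WT vehicle replicate 2 and KO isoproterenol replicate 5 it was 0.20 (adjusted p = 0.957). Myh7 fell less in KO than in WT by 1.295 on the log2 scale without passing (adjusted p = 0.518), and Acta1 (−0.27), Postn (0.45) and Nppa (−0.26) did not pass either (adjusted p = 0.848, 0.834 and 0.642). Without both libraries these were 1.18 for Myh7, −0.11 for Acta1, −0.17 for Postn, whose sign turned, and −0.16 for Nppa, and none passed. In simulated counts with 100 genes changed at each size, this test recovered 28% of the genes whose response differed 1.5-fold and 62% of those that differed 2-fold. Smaller differences were not simulated.

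The size of the response was compared as a single score, the mean log2 change over the 2801 genes that passed for the average isoproterenol effect, each counted in its direction. It was 0.377 in WT and 0.372 in KO, a difference of −0.00571 (exact permutation of genotypes within treatment, two-sided p = 0.906, 63504 arrangements). This compares the responses and not the levels. Under vehicle the underlying level per library was −0.608 to −0.559 in WT and −0.538 to −0.512 in KO, without overlap. That difference in level was not tested. Over the lists of fetal and hypertrophy genes and of extracellular matrix and fibrosis the scores were 0.561 in WT and 0.729 in KO (exact permutation p = 0.581). Of the 37 lists, 13 differed between the responses in the camera test, and none did with an estimated correlation or in fry. The matrix list was among them, with a median of 0.40 higher in KO (adjusted p = 3.92e-04, adjusted p = 0.642 with an estimated correlation). Without the libraries that stood apart its median was −0.04 (adjusted p = 0.984). The list of nuclear-encoded oxidative phosphorylation had a median of −0.13 (adjusted p = 1.57e-05, adjusted p = 0.642 with an estimated correlation), and without those libraries −0.03 (adjusted p = 0.379). Of the 13 lists, 9 kept their call without them, none with an estimated correlation (smallest adjusted p = 0.141). Among these 9 were circadian clock genes (median 0.40), erythroid and platelet markers (0.58), NRF2 targets (0.19), chaperones of the endoplasmic reticulum (−0.15) and atrial markers (−0.30).

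**Figure D3:**
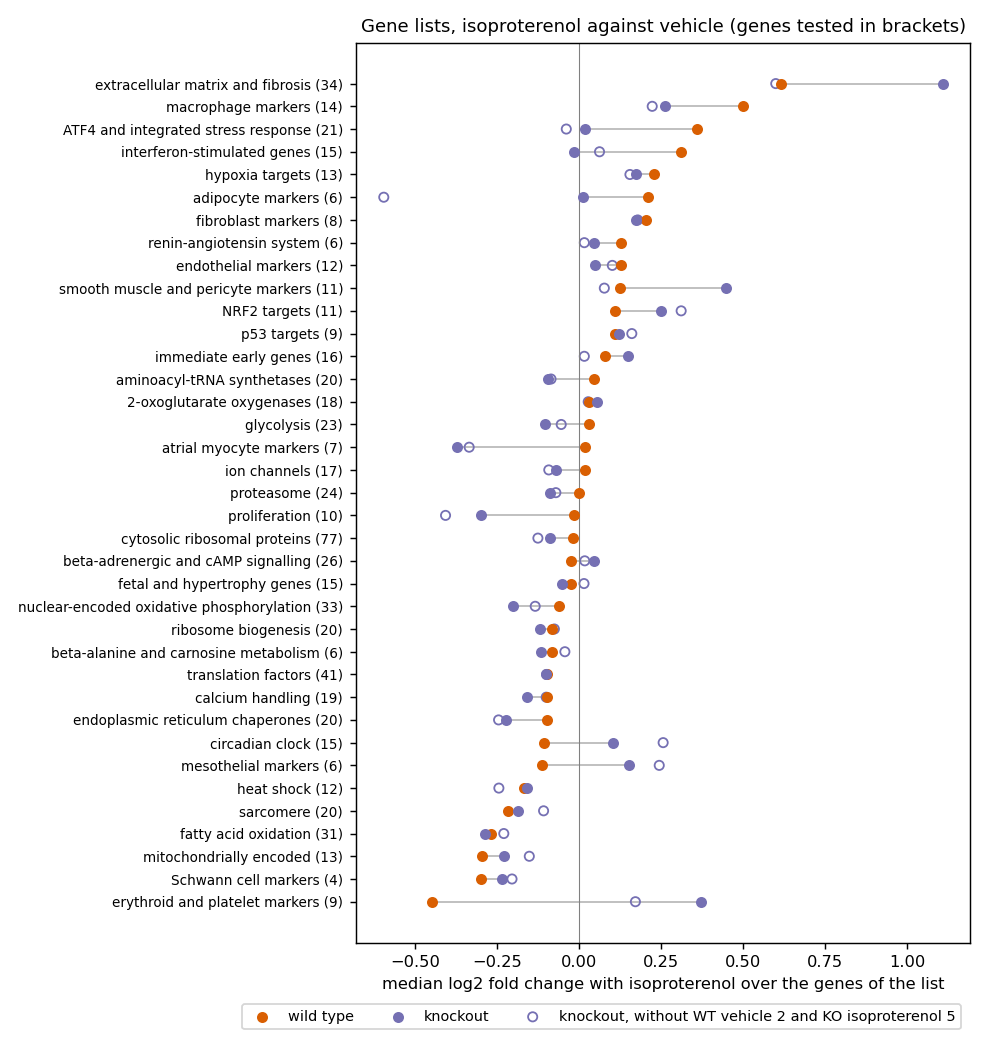
Median log2 fold change with isoproterenol (x axis) over the tested genes of each of 37 lists (y axis, genes tested in brackets) in WT and KO (filled points), and in KO without WT vehicle replicate 2 and KO isoproterenol replicate 5 (open points). The matrix list stood at 0.62 in WT and 1.11 in KO, and at 0.60 in KO without those libraries.

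Under vehicle, few genes besides Ogfod1 passed the test between KO and WT hearts, while 1236 genes had an unadjusted p under 0.05 in edgeR. Cenpf, which encodes a large protein of the centromere and nuclear envelope, was lower in all 5 KO libraries, at 20.0 ± 1.57 against 36.3 ± 5.93 CPM (SD, n = 5; log2 fold change −0.86, SE 0.0951, adjusted p = 7.11e-06). The Wnt signalling gene Dixdc1 was lower (−0.66, SE 0.108, adjusted p = 0.00235) and the tetraspanin gene Tspan12 higher (0.48, SE 0.0847, adjusted p = 0.00595). The short non-coding RNAs Rnu12, the U12 RNA of the minor spliceosome (2.17, SE 0.244, adjusted p = 6.76e-06), and Snord17, a box C/D small nucleolar RNA (1.58, SE 0.236, adjusted p = 0.00593), were higher. Rnu12 was counted 8 to 16 times per WT vehicle library. In total 9 genes were higher and 10 lower in KO by edgeR. Upper quartile scaling gave 9 higher and 6 lower, DESeq2 29 and 43, limma-voom with quality weights 19 and 24, no filter 38 and 79, and 2 surrogate variables 25 and 23. Snord17 lost its call in a fit of only the 2 groups compared. Further calls were Slc38a1 (0.49), a glutamine transporter gene, Nav3 (0.48) and Ugp2 (0.38) among the higher, and Lgals4 (−0.59), Sorcs2 (−0.59), Ptp4a3 (−0.46), the histone deacetylase gene Hdac4 (−0.39), the potassium channel gene Kcnj5 (−0.37) and Ezr (−0.35) among the lower. These 9 calls each ended on leaving out 5 or more of the 10 libraries in turn, whereas the log2 fold change kept its sign. The count fell to 10 without KO vehicle replicate 5, 11 without KO vehicle replicate 4 or WT vehicle replicate 5 and 12 without WT vehicle replicate 4.

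The markers of hypertrophy did not pass under vehicle. Myh7 had a log2 fold change of −1.18 (SE 0.246, adjusted p = 0.0977), Acta1 0.90 (SE 0.209, adjusted p = 0.146), Nppb 0.71 (SE 0.215, adjusted p = 0.279) and Nppa 0.24 (SE 0.0881, adjusted p = 0.417). In DESeq2 the first of these passed at adjusted p = 0.00125 and Acta1 at 0.0166, and both passed in limma-voom (adjusted p = 0.00220 and 0.0191). Col1a1 (0.07), Col3a1 (−0.01), Postn (0.23) and Myh6 (−0.29) did not pass (adjusted p = 0.992, 0.996, 0.927 and 0.258).

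Ion channel genes were lower as a group in KO under vehicle. Only Kcnj5 of 17 passed over all genes, and 8 passed adjusted over the list alone, with Kcnk3 (log2 fold change −0.27) and Kcnj2 (−0.37) next by p. The median was −0.23 (camera adjusted p = 9.08e-07), and this call held with an estimated correlation (adjusted p = 0.0429). Without WT vehicle replicate 2 and KO isoproterenol replicate 5 no member passed in edgeR and the median was −0.16 (adjusted p = 0.119 with an estimated correlation). No atrial marker of 7 passed over all genes and 5 were higher adjusted over the list alone, with Myl4 at 0.41 and a median of 0.28 (adjusted p = 7.15e-07, adjusted p = 0.0992 with an estimated correlation). Circadian clock genes gave 3 of 15 lower adjusted over the list alone and none over all genes, with Hlf at −0.38 (median −0.25, adjusted p = 2.92e-04, adjusted p = 0.0992 with an estimated correlation). No gene of the ATF4 and integrated stress response passed in either count among 21 (median 0.26, adjusted p = 4.57e-05, adjusted p = 0.166 with an estimated correlation), and the asparagine synthetase gene Asns had a log2 fold change of 1.29 (adjusted p = 0.348). Cytosolic ribosomal protein genes gave 0 of 77 in either count (median 0.06, adjusted p = 0.00299, adjusted p = 0.714 with an estimated correlation, and adjusted p = 0.386 without both libraries that stood apart), and translation factors 0 of 41 (median −0.02, adjusted p = 0.459). Aminoacyl-tRNA synthetases gave 0 of 20 (median 0.11, adjusted p = 0.00299, adjusted p = 0.427 with an estimated correlation).

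Under isoproterenol, KO hearts had higher Enah and lower Dbh, Pirt and Kcnj5 than WT hearts. Enah, which regulates actin filaments, measured 142 ± 19.0 against 98.2 ± 5.95 CPM (SD, n = 5; log2 fold change 0.53, SE 0.0818, adjusted p = 0.00237). Dbh, dopamine beta-hydroxylase of noradrenaline synthesis, had a log2 fold change of −0.98 (SE 0.170, adjusted p = 0.00544), Pirt −0.84 (SE 0.130, adjusted p = 0.00237) and Kcnj5 −0.48 (SE 0.0788, adjusted p = 0.00400), each lower in all 5 KO libraries than the WT mean. Cenpf was lower here too, at 48.8 ± 4.74 against 68.9 ± 6.38 CPM (−0.50, SE 0.0915, adjusted p = 0.0154). Its call was lost without KO isoproterenol replicate 4 (adjusted p = 0.0512). In total 8 genes were higher and 19 lower in KO by edgeR, and DESeq2 gave 71 higher and 62 lower, limma-voom with quality weights 48 and 33, no filter 151 and 99, and 2 surrogate variables 22 and 23. Other calls were the Y RNA gene Rny3 (1.79), Tiam2 (0.65), Fam126b (0.50), Kirrel (0.49), Igfbp6 (0.44), Creb5 (0.39) and the growth factor receptor gene Igf1r (0.35) on the higher side. Grrp1 (−0.88), Abca4 (−0.84), Gsg1l (−0.48), Rgs6 (−0.45) and Asb18 (−0.41) were on the lower side. These 12 calls each ended on leaving out at least 1 of the 10 libraries in turn, with no change of sign. The number of calls ranged from 10 without WT isoproterenol replicate 3 to 55 without WT isoproterenol replicate 1, and was 11 without KO isoproterenol replicate 4, 12, 15 and 17 without WT isoproterenol replicates 4 and 5 and KO isoproterenol replicate 2, and 47 without KO isoproterenol replicate 3.

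Among the lists, ion channels again gave lower members in KO under isoproterenol, with Kcnj5 and Kcnq1 (log2 fold change −0.39) past the test of 17 and 5 adjusted over the list alone (median −0.17, camera adjusted p = 3.30e-06, adjusted p = 0.0785 with an estimated correlation). The call of Kcnq1 (adjusted p = 0.0252) ended on leaving out any of 7 libraries in turn. No matrix gene of 34 passed in edgeR over all genes and 13 were higher adjusted over the list alone (median 0.57, adjusted p = 4.55e-12, adjusted p = 0.362 with an estimated correlation). Without KO isoproterenol replicate 5 and WT vehicle replicate 2, 1 matrix gene was higher and the median was 0.14 (adjusted p = 5.68e-04, adjusted p = 0.548 with an estimated correlation). Nuclear-encoded oxidative phosphorylation gave 0 of 33 in both counts (median −0.13, adjusted p = 2.40e-08, adjusted p = 0.546 with an estimated correlation). KO isoproterenol replicate 5 lay below the other 4 libraries of its group on this list, by a median of −0.26. Without the same 2 libraries the median was −0.08 (camera adjusted p = 7.23e-04, adjusted p = 0.712 with an estimated correlation). Enah was the only member of 15 that passed in the fetal and hypertrophy list, over all genes and adjusted over the list alone (median 0.11, adjusted p = 0.0268, adjusted p = 0.226 with an estimated correlation). Cytosolic ribosomal protein genes gave 0 of 77 in both counts (median 0.00, adjusted p = 0.722, and without both libraries adjusted p = 0.0370, adjusted p = 0.917 with an estimated correlation). Myh7 (0.11), Acta1 (0.63), Nppa (−0.02), Nppb (0.12), Myh6 (0.00), Col1a1 (1.78), Col3a1 (0.73) and Postn (0.68) did not pass, with adjusted p-values from 0.259 to 0.995. Without KO isoproterenol replicate 5 and WT vehicle replicate 2 the log2 fold changes were 0.38 for Col1a1, 0.07 for Col3a1 and 0.09 for Postn.

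Both knockout comparisons shared 4 lower genes, the deleted Ogfod1 and Cenpf, Kcnj5 and Gm36827, and 0 higher genes. Leaving out Ogfod1, whose place in both was set by the design, the 3 shared genes stood against 0.0109 for independent lists (Fisher's exact test, p = 1.24e-07). Genes are not independent replicates and both comparisons come from 1 fit, so that this p-value only describes the overlap. The vehicle call of Kcnj5 was lost without 8 of the 10 libraries in turn. DESeq2 gave 5 shared higher genes and 7 shared lower genes, Ogfod1 included. Across all tested genes, which are not independent replicates, the log2 fold changes of the knockout under the treatments correlated at r = 0.181 (Spearman 0.115).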

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

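The tests of single libraries and of Myh7 reported here were chosen after the results had been seen.

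KO isoproterenol replicate 5 held high levels of matrix and smooth muscle transcripts, with Col1a1 at 8.57 log2 CPM and Postn at 8.59, against 4.70 to 5.82 and 6.41 to 6.99 in the other 4 libraries. All 20 sarcomere genes were lower than there (nearest −0.230). A lower share of cardiomyocytes with all other cell types raised alike would raise endothelial markers too, but these lay at a median of −0.107 (SE 0.0702). Other lists moved apart, with adipocyte markers at 1.66 (SE 0.673), erythroid and platelet markers at 0.794 (SE 0.199) and the matrix list at 1.05. A lower share of cardiomyocytes with unequal gains of other cell types was not tested. More smooth muscle bearing tissue in the aliquot may be a source: Tagln and Cnn1 were high (7.68 and 6.24 log2 CPM). Acta2 and Myh11 lay above the mean of the other 4 libraries by 2.32 and 1.78 on the log2 scale. Eln, Actg2 and Itga8 lay above it by 5.69, 3.92 and 3.78. The fibroblast genes Dcn, Pdgfra and Tcf21 differed by −0.00639, 0.0169 and 0.229. These single genes go with such tissue, but were picked after the results had been seen. The 11 smooth muscle and pericyte markers moved unequally, with a median of 0.264 (SE 0.522). That list pools smooth muscle with pericyte genes, so that its median cannot decide it. Fat in the aliquot was not tested apart from such tissue. A stronger response of this heart to isoproterenol also stays open: over 2772 responding genes outside the matrix and smooth muscle lists its mean was 0.468 against 0.300 to 0.372 in the other 4, and over 2681 genes chosen without it 0.403 against 0.325 to 0.391. The sarcomere, adipocyte and erythroid lists were not left out, so that tissue make-up can move these means too. The criteria of both open tests were made stricter after their values were seen, and the second choice of genes was added then.

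The fall of Myh7 with isoproterenol in WT ran against its use as a marker of stress. Reads shared with the paralog Myh6 would have moved both genes alike, but Myh7 fell further, by −1.91 on the log2 scale (SE 0.272). Less atrial tissue would lower atrial markers, whose median change was 0.02 (0.0163, SE 0.0683 over 7 genes). That SE treats the genes as independent, while their estimated correlation was 0.444. Reads of the antisense transcript Mhrt may be a source and stay open: Myh7 lost 206.6 CPM (SE 30.2) and Mhrt measured 81.5 ± 11.6 CPM (SD, n = 5) under vehicle and 57.5 ± 7.53 CPM under isoproterenol, a smaller fall that argues against them, but with an unknown strand setting the counted level is no upper limit, a criterion made stricter after the values were seen. An effect of isoproterenol on Myh7 transcription stays open too.

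Single libraries also stood apart from the other 4 of their group by Dixon's ratio, which chance exceeds in about 1 in 20 groups. Of 304 groups of values tested 22 did so, where chance gives 15.2. WT isoproterenol replicate 4 had 43.67 M counts (others 14.6 to 21.2 M), WT isoproterenol replicate 2 a mitochondrial share of 55.46% (59.5 to 60.8) and WT vehicle replicate 2 an mt-Rnr1 share of 11.39% (4.89 to 5.59) and Lars2 at 9.18 log2 CPM (3.56 to 4.26). In log2 CPM, KO isoproterenol replicate 5 had Rps23 at 5.21 (4.82 to 4.87), Adam8 at 0.61 (1.53 to 1.73) and Slc38a1 at 3.77 (4.00 to 4.07). WT isoproterenol replicate 5 had Nppa at 8.62 (8.41 to 8.45), Nnt at 2.23 (1.56 to 1.74) and Abca4 at 2.84 (1.85 to 2.11), and replicate 4 had Sfrp5 at 0.58 (1.03 to 1.21). WT vehicle replicate 4 had Wdfy1 at 2.73 (3.43 to 3.49). In KO vehicle, replicate 4 had Eif2s3y at 3.64 (4.31 to 4.57), replicate 2 Dixdc1 at 2.78 (2.31 to 2.41), replicate 3 Kcnj5 at 4.95 (4.67 to 4.73) and Rny3 at 0.31 (0.99 to 1.25), and replicate 1 Ezr at 4.71 (4.86 to 4.91). In KO isoproterenol, replicate 4 had Eif2s3y at 3.57 (4.36 to 4.59), replicate 1 Tiam2 at 2.80 (3.18 to 3.27) and replicate 3 Fam126b at 4.08 (3.72 to 3.77).

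The isoproterenol responses of the genotypes differed in 13 lists by camera, none of them with an estimated correlation or by fry. The adjusted p-values were 3.92e-04 for extracellular matrix, 1.57e-05 for nuclear-encoded oxidative phosphorylation, 0.0176 for glycolysis (0.01763) and for cytosolic ribosomal proteins (0.01762), 0.00231 for aminoacyl-tRNA synthetases, 0.0187 for ATF4 targets and 0.00897 for endoplasmic reticulum chaperones. They were 0.0155 for NRF2 targets, 0.00175 for circadian clock genes and for interferon-stimulated genes, 0.0235 for the proteasome, and 2.75e-06 for erythroid and platelet markers and for atrial myocyte markers.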

How the results depend on the processing

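The alternatives were planned, except that WT vehicle replicate 2 and KO isoproterenol replicate 5 were left out together after the data had been seen. Calls for isoproterenol stayed within 1.5 times, at 882 to 1246 in WT and 1001 to 1416 in KO without each library in turn. Knockout calls under vehicle (19) came to 72 with DESeq2, 43 with quality weights, 117 with no filter, 48 with 2 surrogate variables, 38 without both libraries, and 10 to 18 without each library. Under isoproterenol (27) they came to 133, 81, 250, 45 and 50 in that order, and 10 to 55 without each library. Genes whose response differed by genotype (0) numbered 34 with no filter and 4 without both libraries (Aox1, Fam198b, Gimap4 and Sik3), and 0 to 1 without each library: Rnu12 without KO vehicle replicate 1 (−1.90) and Aox1 without KO isoproterenol replicate 5 (0.69). The cause was not tested. With an estimated correlation 1, 1, 1, 0 and 0 lists passed, in the order WT response, KO response, knockout under vehicle, knockout under isoproterenol and difference of responses, from 14, 20, 17, 12 and 13. With fry 16, 19, 6, 3 and 0 passed in that order, and 13 of the 14 camera calls of the WT response were kept. The sarcomere list changed direction in the difference of responses without both libraries (adjusted p = 0.0289, adjusted p = 0.716 with an estimated correlation), and Lars2 with surrogate variables (0.29). The difference in response size (−0.00571) was 0.168 over the hypertrophy and matrix lists, and −0.0278 to 0.0297 without each library, positive without KO vehicle replicate 1 (0.0187) or 5 (0.00723) or KO isoproterenol replicate 1 (0.0186), 3 or 4 (0.00424), with exact permutation p from 0.526 to 0.987. At an adjusted p under 0.1 the isoproterenol calls shared 403 lower genes (250) and the knockout calls 3 higher genes (0). The knockout calls shared 5 higher and 7 lower genes (4) with DESeq2, and 1 higher without both libraries. The planned covariate of Y-linked genes was not run, since it was meant for a mix of sexes and all 20 libraries expressed Y-linked genes. No paired analysis was possible because replicate numbers give only the order of the records. Counts of a few reads, as for Rnu12 and Snhg11, limit the precision of low genes.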

Other observations

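The set of small nuclear and small nucleolar RNAs, which was not among the fixed lists, and the tests of Cenpf, of other short RNAs and of other groupings were chosen after the results had been seen, and the test of the host genes before its own result.

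Small nuclear and small nucleolar RNAs, which guide splicing and RNA modification, lay higher in KO than in WT hearts under vehicle. Over 41 tested genes the median log2 fold change was 0.46 (SE 0.129), 80.5% were higher and 4 passed the edgeR test. The set was examined because of such calls, so that they are no separate evidence. Over the 37 others the median was 0.38 (SE 0.120) and 78.4% were higher. These come from the same libraries as the 4 called genes, so that they are not independent evidence either. The p-values below take no account of choosing this set after the results had been seen. The mean score of these 37 genes per library was −0.0310 ± 0.0873 in WT vehicle, 0.127 ± 0.138 in WT isoproterenol, 0.345 ± 0.136 in KO vehicle and 0.310 ± 0.133 in KO isoproterenol (SD, n = 5). The exact permutation p between genotypes was 0.00794 under vehicle, the smallest that 252 arrangements can give (adjusted p = 0.0317 over 4 comparisons), and 0.0794 under isoproterenol (adjusted p = 0.106). With isoproterenol it was 0.0794 in WT (adjusted p = 0.106) and 0.683 in KO.

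More host transcript would raise the 30 genes that contain them on the same strand, whose median was −0.03 (−0.034, SE 0.0333). Reads from introns of the hosts may not have been counted for the host genes, and the strand setting is unknown. Host reads therefore stay open. Better recovery of all short RNAs in the KO vehicle libraries may be a source and stays open. The 44 other non-coding genes under 400 nucleotides had a median of −0.00112 (SE 0.191). Of them 50% were higher, against 50.8% of all tested genes. As a set they showed no rise, but their spread was too wide to decide it, by a criterion made stricter after the value was seen. The short RNA gene Rny3 measured 0.886 CPM in WT vehicle and 1.91 CPM in KO vehicle. It was picked singly and does not stand for the other short RNAs, which moved both ways. A difference between genotypes stays open too, and the recovery of these classes alone was not tested.

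Cenpf rose with isoproterenol in WT (log2 fold change 0.93, SE 0.0925, edgeR adjusted p = 1.46e-07) and in KO (1.29, SE 0.0950, adjusted p = 5.43e-10), and the difference did not pass (0.36, adjusted p = 0.518). Fewer dividing cells in KO might lower Cenpf under vehicle, but the mean of 10 proliferation genes differed by 0.0637 (SE 0.191, exact permutation p = 0.738), against −0.86 for Cenpf. These genes had a median of 0.39 log2 CPM, against 5.30 for Cenpf.

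Other groupings of the same libraries, 100 per comparison with the real one, were refitted. Only the real grouping gave as many calls for isoproterenol in WT (1304, highest other 92) and in KO (1344, highest other 185). The same held for knockout under vehicle (19, highest other 2) and knockout under isoproterenol (27, highest other 8). Ogfod1, lower by design, was in both knockout counts. A share of 1 in 100 is the smallest that these groupings can give. Other groupings mix the true groups, so that real differences widen their spread, and single calls were not tested in this way. For the difference between responses, 8 of 100 gave at least the 1142 genes at an unadjusted p under 0.05, with a highest other of 1652, so that chance was not excluded.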
